A study of Danio rerio with 20 samples.

How the data were processed

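DNA methylation was measured by targeted bisulfite sequencing in gonads of zebrafish of the AB strain at 90 days of age. Bisulfite treatment turns unmethylated cytosine into a base read as thymine, so the share of reads that still show cytosine at a CpG gives its methylation. There were 20 samples in 4 groups of 5. Larvae had been given lipopolysaccharide (LPS, a component of the outer membrane of Gram-negative bacteria) from Pseudomonas aeruginosa or had served as controls, in a set named 3H and a set named 6H. The labels do not state what 3H and 6H stand for, the sex of the fish, or whether samples came from separate fish or families. The p-values therefore measure the spread between these samples, which may in part be technical.

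Per the labels, DNA was extracted with phenol and chloroform and converted with a commercial bisulfite kit, and libraries followed a protocol for amplicon sequencing with an index kit. Trim Galore 0.4.5, FastQC 0.11.6, Bowtie2 and Bismark are named in the submitters' processing notes, with the genome build GRCz11. The settings of these tools are not given in the sources used here. The deposited tables give, for each CpG position, the percent methylated and the counts of methylated and unmethylated reads, per the file layout. The deposited counts were used as they stand, and the deposited percent values equalled the percent recomputed from the counts. The tables held 4504 position records at 456 distinct positions. Positions are on GRCz11, counted from 1. No genome or annotation of this build was used, so regions are named by position and were not assigned to genes.

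A CpG was tested if it had at least 10 reads in at least 4 of the 5 samples of every group. A sample under 10 reads at a CpG was left out at that CpG. Tested CpGs at most 500 bp apart were joined, and regions with at least 3 CpGs were named, which gave 135 CpGs in 8 regions. The value of a region in a sample was the unweighted mean of the percent methylated over its CpGs. Single CpGs were tested with edgeR 4.0.16 (R 4.3.3), by the quasi-likelihood test on methylated and unmethylated counts with 1 intercept per sample, all 20 samples in 1 fit and Benjamini-Hochberg adjustment over the CpGs. Regions were compared by two-sided exact permutation tests of the difference of group means, adjusted over the 8 regions. The difference between the LPS effects of the 2 sets was tested by permuting set labels within each treatment after centring each set, which is approximate because the centre is estimated. The threshold was an adjusted p of 0.05. The tests of the comparisons, the alternatives and the naming rule were set before the data were examined, except where a later choice is stated.

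The naming rule took every region. In each comparison, CpGs past the threshold among the 5 smallest p of each region were named. Where none passed, the CpG with the smallest p in each region was named with its difference. Genes of 3 lists fixed in advance could not be matched to the regions without an annotation of the build, so no result is given by list. Alternatives were coverage minimums of 5, 30 and 100 reads, CpGs covered in all 20 samples, limma 3.58.1 on the log2 ratio of methylated to unmethylated reads with 0.5 added to each, an exact permutation test per CpG, fits on the compared samples alone, pooled reads, medians, a logit scale, a replicate block and leaving out each sample. An alternative without CpGs at separate levels was added after seeing the data. It left out CpGs at which the largest gap between neighbouring sample values was at least 10 percentage points with at least 2 samples on each side.

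Both tests were tested on simulated data. In 10 simulated runs per size of change, 20 of 135 CpGs were changed in 3H LPS samples. On the natural log-odds scale, edgeR recovered 76.5% of changes of 0.5 and 99% of changes of 1. False calls averaged 0.7 and 0.6 per run. The changed CpGs were drawn only from CpGs away from both ends of the methylation scale and without a low mean depth. No CpG near 0% was changed, so these shares do not show the power in regions near 0%. The shares hold only for the spread between samples that was simulated. The exact test of 5 against 5 passed 0.05 in 6.5% of 200 simulated comparisons without a shift, and the test between sets in 7% of 200 without an interaction. No samples held identical values. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.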

Results

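Methylation was measured at 8 short regions of the zebrafish genome in gonads of adult fish, 5 samples each of 3H controls, 3H LPS, 6H controls and 6H LPS. The study's title names its subject as sex differentiation under inflammation caused by LPS. Each sample held between 419055 and 2046055 methylation calls, and between 99.85% and 99.97% of them lay at the 135 tested CpGs. The depth differed between regions. The median number of reads per CpG of a sample reached from 1993 to 27409 in the chromosome 10 region, but from 22 to 4758 in the first of the 2 chromosome 5 regions.

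The regions fell into 3 kinds by level. Regions on chromosome 10 (44956550 to 44956872, 9 CpGs), chromosome 18 (39636122 to 39636564, 18 CpGs) and chromosome 19 (27019198 to 27019584, 7 CpGs) were mostly methylated, with means over all samples of 61.8% ± 4.05 (SD, n = 20), 72.7% ± 6.43 (SD, n = 20) and 74.5% ± 0.896 (SD, n = 20). On chromosome 18, 3 CpGs at or near 0% had too few reads in 2 control samples, and over the 15 CpGs covered in all samples the mean was 85.4% ± 2.70 (SD, n = 20). The region on chromosome 24 (21640622 to 21640889, 13 CpGs) had a mean of 16.6% ± 3.49 (SD, n = 20), and the first region on chromosome 5 (44944720 to 44945152, 24 CpGs) had 17.9% ± 2.96 (SD, n = 20). Regions on chromosome 23 (24973689 to 24974060, 19 CpGs), chromosome 3 (54607068 to 54607470, 26 CpGs) and the second region on chromosome 5 (67992821 to 67993138, 19 CpGs) were almost unmethylated, at 0.604% ± 0.0897, 0.427% ± 0.136 and 0.604% ± 0.0921 (SD, n = 20 each). No measure of bisulfite conversion was used here, so values near 0 include unconverted and misread bases.

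**Figure D1:**
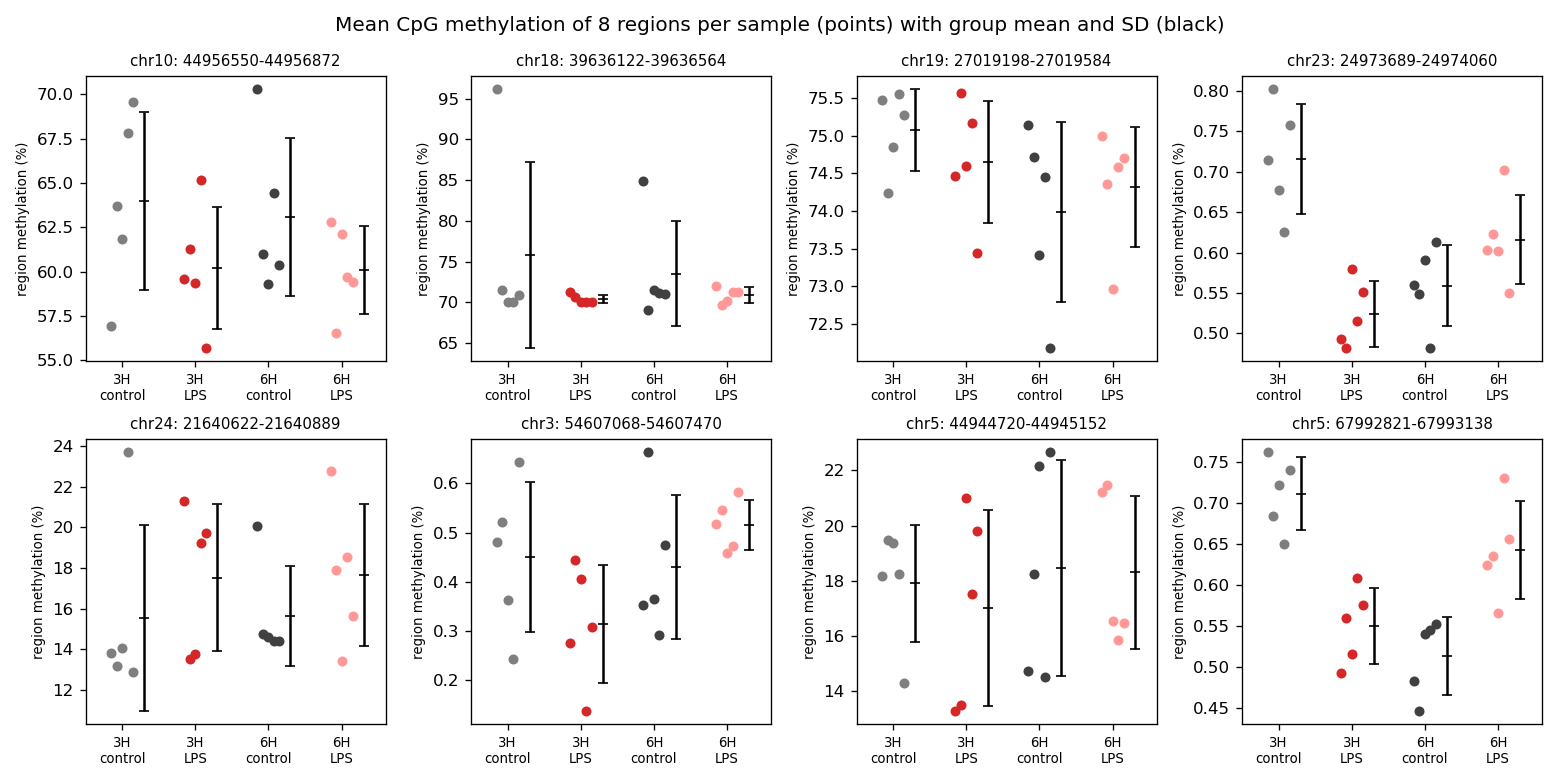
Mean CpG methylation in percent (vertical axis, a different range in each panel, not starting at 0) of each sample (points) in the 4 groups (horizontal axis), with the group mean and SD in black, for the 8 regions. The chromosome 18 value of 3H control replicate 1 is 96.2%, and all values in the chromosome 23 panel lie between 0.481% and 0.803%.

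The comparison of LPS with control samples of the 3H set asks whether exposure of larvae was followed by a difference in gonadal methylation. Of the 8 regions, the nearly unmethylated regions on chromosome 23 and the second on chromosome 5 were lower in LPS samples. Chromosome 23 had 0.716% ± 0.0685 (SD, n = 5) in controls and 0.524% ± 0.0408 (SD, n = 5) in LPS samples, a difference of -0.192 percentage points (exact permutation p = 0.00794, adjusted p = 0.0317). The second chromosome 5 region had 0.712% ± 0.0450 (SD, n = 5) and 0.550% ± 0.0463 (SD, n = 5), a difference of -0.162 percentage points (exact permutation p = 0.00794, adjusted p = 0.0317). In both regions every LPS sample lay below every control, and this p is the smallest that 5 against 5 samples can give. The differences of medians were -0.200 and -0.163, but many arrangements of 5 against 5 samples tie at the largest possible one. The test of medians therefore could not call 2 regions alone over 8 (permutation test of medians, adjusted p = 0.190 for both). Neither region passed without LPS replicate 1, 2, 4 or 5. The differences there stayed from -0.198 to -0.181 and from -0.176 to -0.147 percentage points, with exact permutation p = 0.0159 and 0.00794 and adjusted p = 0.0635 for both.

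The mostly methylated regions did not pass. Chromosome 10 had 64.0% ± 5.02 (SD, n = 5) in controls and 60.2% ± 3.45 (SD, n = 5) in LPS samples, a difference of -3.74 percentage points with an exact permutation interval from -10.2 to 2.93, and -2.34 without control replicate 5. Without position 44956872, where sample values fell on separate levels, the difference was -0.713. Chromosome 19 differed by -0.428 percentage points, with an interval from -1.46 to 0.544, and by -0.127 without LPS replicate 5. Chromosome 18 had 75.8% ± 11.4 (SD, n = 5) and 70.4% ± 0.514 (SD, n = 5). The difference of -5.35 percentage points rests in part on 3 CpGs at or near 0% that had too few reads in 3H control replicate 1. Over the 15 CpGs covered in all samples it was -2.57, still with this sample. Without 3H control replicate 1 the difference was -0.249. The first chromosome 5 region differed by -0.891 percentage points, where the 3H LPS samples had medians as low as 22 reads. Its difference turned to 0.0472 without LPS replicate 1. No single CpG passed with edgeR (0 of 135, lowest adjusted p = 0.0609), while 14 had an unadjusted p under 0.05 against 6.75 expected. Limma called none, with 17 at an unadjusted p under 0.05. The exact test per CpG had 10, but it could call a CpG only if 22 reached its smallest p of 0.00794, and 2 did. The smallest p values were at position 54607163 of chromosome 3, at 0.249% ± 0.131 (SD, n = 5) in controls and 0.972% ± 0.602 (SD, n = 5) in LPS samples, and at position 44956872 of chromosome 10. The CpG with the smallest p in each other region did not pass either (edgeR adjusted p from 0.109 to 0.698). These differences were -0.487 percentage points at 24973894 of chromosome 23 and -0.525 at 67992872 and -8.71 at 44945105 of chromosome 5. They were -3.34 at 39636523 of chromosome 18 (-1.84 without control replicate 1) and -2.46 at 27019548 of chromosome 19 (-1.08 without LPS replicate 5). At 21640624 of chromosome 24 the difference was 13.7 (22.6 without control replicate 4, 9.30 without LPS replicate 1). Sample values at this last CpG fell on separate levels, with 1 of 5 controls and 3 of 5 LPS samples on the upper level.

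In the 6H set, 1 CpG differed between LPS and control samples, position 44956872 of chromosome 10. It was at 45.3% ± 1.95 (SD, n = 5) in controls and 0.275% ± 0.0671 (SD, n = 5) in LPS samples (edgeR log2 odds difference -8.21, adjusted p = 0.00256), with a median of 5129 reads per sample. All 5 LPS samples lay below all 5 controls. In the 3H set the same CpG was at 37.2% ± 20.7 (SD, n = 5) in controls and 9.19% ± 20.1 (SD, n = 5) in LPS samples (edgeR adjusted p = 0.0609). There, control replicate 1 was at 0.271% and LPS replicate 4 at 45.1%. The nearest tested CpG, 47 bp away, was between 91.7% and 96.7% in all 20 samples. The values of this CpG fell on 2 separate levels, and an exact permutation test per CpG adjusted over 135 CpGs did not call it (adjusted p = 0.536), nor could it, as 2 CpGs reached its smallest p and 22 were needed.

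**Figure D2:**
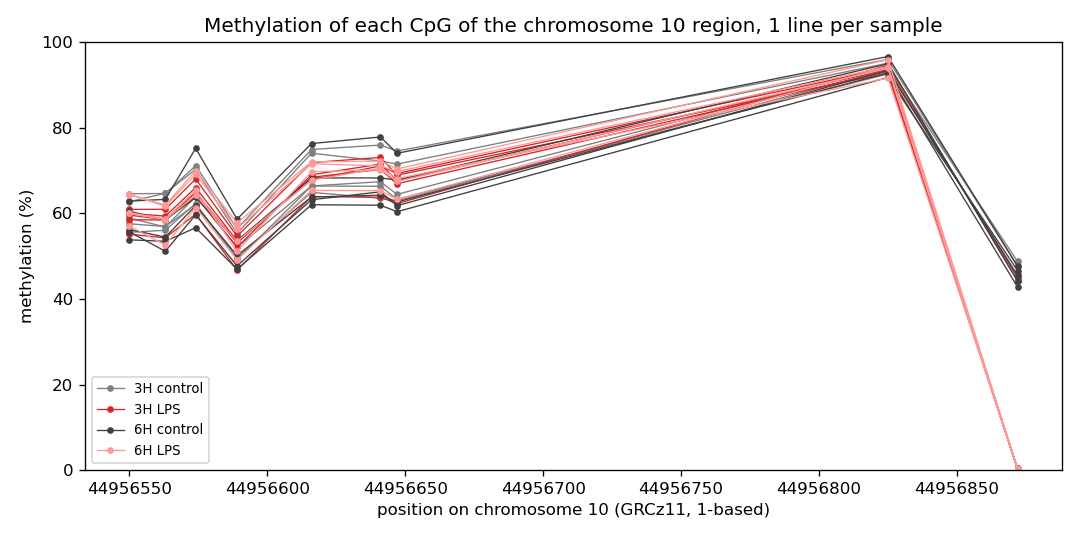
Methylation in percent (vertical axis) of the 9 tested CpGs of the chromosome 10 region by position on GRCz11 (horizontal axis), with 1 line per sample coloured by group. At the last CpG, 10 samples lie between 42.8% and 48.8% and 10 between 0.131% and 0.376%, while the lines do not part in this way at the other CpGs.

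No region passed in the 6H set. The second chromosome 5 region had 0.513% ± 0.0471 (SD, n = 5) in controls and 0.642% ± 0.0597 (SD, n = 5) in LPS samples, a difference of 0.129 percentage points (exact permutation p = 0.00794, adjusted p = 0.0635). Every LPS sample lay above every control there. This p is the smallest that 5 against 5 samples can give, so 1 region alone could not pass over 8. Chromosome 10 differed by -2.98 percentage points (exact permutation interval -8.20 to 1.80), and by -1.17 without control replicate 1. Without the CpG at separate levels the difference was 2.28, in the other direction. Chromosome 18 differed by -2.63 percentage points with the 3 sparsely read CpGs and by 0.190 without them. Chromosome 24 differed by 2.01 percentage points (exact permutation interval -2.73 to 6.17), and by 0.724 without LPS replicate 1 and 3.12 without control replicate 1.

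Over both sets together, position 44956872 of chromosome 10 again was the 1 CpG called (edgeR log2 odds difference -7.50, adjusted p = 0.000415), with a difference of -36.5 percentage points. The exact permutation test per CpG did not call it (adjusted p = 0.0850). Of the 10 controls, 9 were on the upper level, and of the 10 LPS samples, 9 were on the lower level. No region passed, the lowest p being that of chromosome 10 at -3.36 percentage points (permutation p = 0.0692, adjusted p = 0.393). Without the CpGs at separate levels no CpG was called, and chromosome 10 differed by 0.785 percentage points.

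Controls of the 6H set were compared with controls of the 3H set to show how far the sets differed without LPS. Chromosome 23 was at 0.559% ± 0.050 (SD, n = 5) in 6H and 0.716% ± 0.0685 (SD, n = 5) in 3H controls, a difference of -0.157 percentage points (exact permutation p = 0.00794, adjusted p = 0.0317). The second chromosome 5 region was at 0.513% ± 0.0471 (SD, n = 5) and 0.712% ± 0.0450 (SD, n = 5), a difference of -0.199 percentage points (exact permutation p = 0.00794, adjusted p = 0.0317). The differences of medians were -0.155 and -0.181, and the test of medians again could not call 2 regions alone (permutation test of medians, adjusted p = 0.190 for both). Neither region passed without any 1 of the 6H controls. The differences there stayed from -0.170 to -0.138 and from -0.208 to -0.182, with exact permutation p = 0.0159 and 0.00794 and adjusted p = 0.0635 for both. In the 3H set, LPS and control samples had differed by -0.192 and -0.162 percentage points in these regions. The 3 mostly methylated regions did not pass, with chromosome 19 at -1.09 percentage points (exact permutation interval -2.61 to 0.217) and at -0.642 without 6H control replicate 5. No CpG passed with edgeR (0 of 135, lowest adjusted p = 0.0967). At an unadjusted p under 0.05 there were 12 with edgeR, 12 with limma and 9 with the exact test. Limma called none, and the exact test would have needed 22 CpGs at its smallest p, which 3 reached. The CpG with the smallest p in each region differed by 0.226 percentage points at 54607309 of chromosome 3, -0.381 at 24973957 of chromosome 23 and -0.425 at 67992891 of chromosome 5. The others were 1.78 at 21640811 of chromosome 24, -2.28 at 27019198 of chromosome 19 and 1.60 at 44944858 of chromosome 5. At 39636210 of chromosome 18 the difference was -4.08, but -0.923 without 3H control replicate 1, which was at 94.8%. At 44956563 of chromosome 10 it was -3.67, and -2.42 without 6H control replicate 5.

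The LPS effect differed between the sets in the same 2 regions. This comparison shares the 3H controls with the 2 that called these regions before, and 3H controls were the highest group in both. The calls are therefore not independent. The effect in 6H minus that in 3H was 0.249 percentage points on chromosome 23 (permutation p = 9.45e-05, adjusted p = 0.000378). In the second chromosome 5 region it was 0.291 (permutation p = 3.15e-05, the smallest these permutations can give, adjusted p = 0.000252). In the 3H set LPS samples were below controls in both. In the 6H set they were above, by 0.0573 percentage points (exact permutation p = 0.119, and 0.0357 without LPS replicate 4) and by 0.129. The chromosome 3 region, also nearly unmethylated, had a difference between sets of 0.222 percentage points (permutation p = 0.0568, adjusted p = 0.151). Its LPS effects were -0.136 in the 3H set and 0.0858 in the 6H set. This region passed without 6H control replicate 2 (permutation test, adjusted p = 0.0331). With edgeR, 1 CpG passed, position 54607259 of the nearly unmethylated chromosome 3 region (log2 odds difference 3.88, adjusted p = 0.0303). Its levels were 0.925% ± 0.889 (SD, n = 5) in 3H controls, 0.199% ± 0.140 (SD, n = 5) in 3H LPS, 0.155% ± 0.0146 (SD, n = 5) in 6H controls and 0.698% ± 0.447 (SD, n = 5) in 6H LPS samples. The call was lost when any of 11 samples was left out, and with the exact permutation test per CpG (adjusted p = 0.0553).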

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

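The tests of explanations here were chosen after the results they bear on were seen, except the correlation between the 2 nearly unmethylated regions. Of 100 groups of 5 samples tested for a single distant sample, 13 were flagged, where chance gives about 5 if groups are independent. They were not, since a region and a named CpG within it can flag the same sample. The 2 numbers therefore do not show an excess of distant samples.

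Position 44956872 of chromosome 10 was flagged because 1 sample of each 3H group stood apart, control replicate 1 at 0.271% and LPS replicate 4 at 45.1%. A library-wide difference in conversion is argued against by the chromosome 23 region, where controls and LPS samples differed by 0.0672 percentage points. A candidate explanation is a sequence variant at the CpG carried in 1 of 2 copies. Ratios to the nearest tested CpG on the upper level were between 0.461 and 0.517, at most 0.0394 from 0.5. These ratios bear on the upper level only. The 10 samples on the lower level were between 0.131% and 0.376%, so under this explanation they would lack the CpG on both copies. No sample lay at the level of the nearest tested CpG, 91.7% to 96.7%, and the lower level was not tested. LPS exposure stays open and cannot be told apart from a difference in parentage between the fish, since 2 samples lay at the level of the other treatment and the labels name no families or genotypes.

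The regions on chromosome 23 and the second on chromosome 5 were flagged because the LPS effect differed between sets, by 0.249 and 0.291 percentage points. Unconverted or misread bases that differ between groups may account for this. The median CpG of the chromosome 3 region, also near 0, showed the same direction with 0.152 percentage points, although its own permutation p was 0.0666. By the region mean this difference was 0.222 on chromosome 3. Its controls, however, differed between sets by only -0.0208 (exact permutation interval -0.240 to 0.207), against -0.157 on chromosome 23 and -0.199 in the second chromosome 5 region. Deviations of the 2 regions from their group means correlated with Pearson r = 0.291 (permutation p = 0.214) and Spearman rho = 0.274 (permutation p = 0.242), and r was 0.221 without the 2 farthest samples, which does not decide whether libraries within a group vary in this way. An LPS effect that depends on the set also stays open and cannot be told apart from unconverted or misread bases. Of the 38 CpGs, 92.1% had a difference above 0 while 0 passed with edgeR. The share above 0 does not decide this, since the same CpGs make up the region differences that were called.

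The chromosome 18 region was flagged in 3H control replicate 1 at 96.2%, with the other 3H controls between 70.1% and 71.6%. Over CpGs covered in all samples it was at 96.2%, and the other 19 samples were between 82.8% and 86.5%. Read sampling is argued against by the exact 95% binomial interval with the reads of 1 CpG as n, whose lower bound was 92.6%; it covers counting error only. A candidate explanation is that few molecules of this region were amplified, as this library had 191 reads per CpG there and the next lowest had 12.96 times as many. The library was not shallow in total, with 1858242 calls. No biological explanation was tested, since the labels give none for a single sample.

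Other single samples stood apart from their groups. The chromosome 18 region was at 84.9% in 6H control replicate 1, where the 3 sparsely read CpGs at or near 0% were not counted. Over CpGs covered in all samples the 6H controls lay between 82.9% and 85.8%, and this sample did not stand apart. On chromosome 24 the region was at 23.7% in 3H control replicate 4 and 20.1% in 6H control replicate 1, and position 21640624 was at 52.1% and 48.2% in the same samples. The first chromosome 5 region was at 14.3% in 3H control replicate 5. Position 39636210 of chromosome 18 was at 94.8% in 3H control replicate 1, and position 27019198 of chromosome 19 at 81.0% in 3H LPS replicate 5. In 6H control replicate 4, position 24973894 of chromosome 23 was at 0.249%, with the other 6H controls from 0.676% to 0.743%. Position 54607259 of chromosome 3 was at 0.181% in this sample, from 16 methylated of 8841 reads. The other 6H controls were from 0.147% to 0.149% there, so this gap is small and near 0%. The LPS effect at position 54607259 differed between the sets by 1.27 percentage points.

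Other splits of the samples show how often CpG counts as large arise by regrouping. Of 100 splits drawn for each comparison, the real one included, 9 gave at least the 1 CpG called in the 6H set (highest other 2), 5 the 1 called over both sets (highest other 4), and 8 the 1 called for the difference between sets (highest other 2). Chance could not be excluded for these counts. For the 3H set and for the controls the real count was 0, which all 100 splits reached, with highest others of 1 and 2.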

How the results depend on the processing

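The alternative without CpGs at separate levels was chosen after seeing the data; the others were planned. Counts of CpGs were the same under the coverage minimums, CpGs covered in all samples and limma. Without the CpGs at separate levels, the counts of the 6H set and of both sets fell from 1 to 0, because the called CpG was left out. The exact permutation test per CpG called 0 in these 2 comparisons and 0 for the difference between sets. Position 44956872 of chromosome 10 had adjusted p = 0.536 in the 6H set, where 5 against 5 samples limit a p over 135 tests, and 0.0850 over both sets. Position 54607259 of chromosome 3 had 0.0553 for the difference between sets.

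The labels number samples alike in each group but do not say that numbers pair them. Same-numbered samples did not all deviate together (correlations from -0.202 to 0.238 in the 3H set and from -0.163 to 0.126 in the 6H set). The best match had the same number in 3 of 5 cases in the 3H set and 1 of 5 in the 6H set. These values do not settle whether numbers pair the samples. With a replicate block, 1 CpG was called in the 3H set in place of 0. The block called 0 regions in the 3H set, 0 between controls and 0 for the difference between sets, in place of 2 each, because 5 pairs cannot give a p below 0.0625. Comparing medians gave 0 regions in the 3H set and 0 between controls; the cause was not tested.

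Leaving out 1 sample gave from 0 to 2 CpGs in the 3H set, 1 to 2 in the 6H set, 1 to 2 over both sets, 0 to 1 between controls and 0 to 3 for the difference between sets. It gave from 0 to 2 regions in the 3H set, 0 to 2 between controls and 2 to 3 for the difference between sets. The 0 regions of the 3H set came without LPS replicate 1, 2, 4 or 5, and those between controls without any 1 of the 6H controls, each with adjusted p = 0.0635 for both regions in exact permutation tests. The differences kept their size, from -0.214 to -0.170 on chromosome 23 and from -0.177 to -0.147 in the second chromosome 5 region in the 3H set, over all samples left out. Where the call was lost, p was 0.0159 (2 of 126 arrangements) on chromosome 23 and 0.00794 (1 of 126) in the other region. The CpG count of the 3H set was 1 without control replicate 1 or 2 or LPS replicate 2, and 2 without LPS replicate 4. It was 2 in the 6H set without LPS replicate 3 or 5, 2 over both sets without 3H LPS replicate 4, and 1 between controls without 3H replicate 4 or 6H replicate 5. For the difference between sets it was 0 without 3H LPS replicate 1, 2, 4 or 5, 6H control replicate 1, 2, 3 or 4, or 6H LPS replicate 1, 2 or 4. It was 2 without 3H control replicate 3 or 4 or 6H LPS replicate 5, and 3 without 6H control replicate 5. Position 44956872 of chromosome 10 passed in the 3H set without control replicate 1 (adjusted p = 0.00225, edgeR) or LPS replicate 4 (adjusted p = 0.000879, edgeR), the samples out of place there.

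Directions turned only for region differences that had not passed. In the 6H set, chromosome 18 turned to 0.175 with pooled reads, 0.198 at 5 reads, 0.190 at 30 and 100 reads and with CpGs covered in all samples, and 0.0948 with medians, and all but the medians treat the sparsely read CpGs at or near 0% alike in every sample or give them little weight. Without the CpGs at separate levels chromosome 10 turned to 2.28 in the 6H set and 0.785 over both sets. Medians turned chromosome 18 between controls to 0.197, and for the difference between sets chromosome 24 to -2.13 and the first chromosome 5 region to -0.997; the logit scale turned chromosome 24 to -0.0229. The cause was not tested.

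Leaving out 1 sample moved the first chromosome 5 region from -1.89 to 0.0472 in the 3H set, from -1.15 to 0.893 in the 6H set, from -1.02 to 0.000914 over both sets, from -0.487 to 1.55 between controls and from -0.255 to 1.78 for the difference between sets. Chromosome 18 moved from -6.77 to -0.249 in the 3H set, with -0.249 without control replicate 1, from -3.75 to 0.221 in the 6H set, from -5.11 to 2.85 between controls and from -2.38 to 5.57 between sets. Chromosome 19 moved from -0.657 to -0.127 in the 3H set, from -0.115 to 0.674 in the 6H set, from -0.271 to 0.123 over both and from -1.38 to -0.642 between controls. Chromosome 3 moved from -0.0512 to 0.00404 over both sets and from -0.0794 to 0.0273 between controls. Chromosome 10 moved from -5.51 to -2.34 in the 3H set, from -3.92 to -1.17 in the 6H set, from -2.68 to 0.528 between controls and from -0.636 to 2.57 between sets, and chromosome 24 from -0.992 to 2.16 between controls and from -2.02 to 1.13 between sets. Chromosome 24 moved from 1.03 to 4.03 in the 3H set and from 0.724 to 3.12 in the 6H set. Depth limits the first chromosome 5 region most, with 22 reads per CpG in 1 sample.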

Other observations

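Position 27019282 of chromosome 19 was at 17.98% in 3H LPS replicate 5 and 18.5% in 6H control replicate 5, and between 0.0796% and 1.07% in the other 18 samples. These libraries had the fewest reads there, 484 and 270. They held 87 and 50 methylated reads, and the others held from 2 to 90.

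Position 21640624 of chromosome 24 had 6 samples at or above 40.5% and 14 at or below 27.3%. The 6 samples came from all 4 groups.

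Outside the 8 regions, 40 clusters of positions had reads, 34 of them in 1 or 2 samples. A cluster on chromosome 7 (35126017 to 35126415) had reads in all 20 samples, at most 22 at a position, and 81.5% of its 2023 calls were methylated. It did not pass the coverage minimum and entered no comparison.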
